A study of Mus musculus with 24 samples.

How the data were processed

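Total RNA of 24 samples, 3 per tissue and maternal diet, was labelled with biotin and read on single-channel Affymetrix mouse arrays with 45101 probe sets, per the labels. The deposited values are log2 expression values per probe set that the authors made with RMA in R 2.7.0, per the submitters' processing notes. The notes also name MAS5 and do not state its role. Per the labels, the liver arrays and the muscle arrays were normalized separately, so levels were not compared between tissues. The deposited values ran from 2.75 to 15.01, with a median per array of 4.95 to 5.39. No further normalization was applied. Scanner files were not used here.

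Each value column was assigned to its sample through the labels, and 0 columns were left without a sample. Probe sets were named from the platform annotation. Of 45101 probe sets 34945 had 1 gene symbol, 932 had several, 9160 had none and 64 were controls. The gene identifiers of 34741 probe sets were found in a mouse reference gene table of assembly GRCm38.p6, used for names only, and 204 were not. This changed 0 symbols. For each gene the probe set with the highest mean over the 12 arrays of the tissue was used, which left 18193 genes, of which 9010 had more than 1 probe set. Where the probe sets of a called gene chosen by the naming rule differ in sign, the number with the sign of the change is given in Results. For other named genes, and for differences between the tissues, agreement of the probe sets is not given. The 10092 probe sets with no symbol or several were tested apart. No filter on low values was applied.

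Each tissue was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes) on its 12 arrays, with a mean for each of the 4 diets, so that the groups share an estimate of the spread. The 5 contrasts were LP minus NP, LPtau minus LP, NPtau minus NP, LPtau minus NP, and the interaction, which is LPtau minus NPtau less LP minus NP. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. Counts at an unadjusted p under 0.05 are not calls, since chance alone gives on average 5% of those tested. An exact test of a single gene with 3 against 3 arrays cannot give a two-sided p below 0.1, so calls rest on limma's pooling of the spread over genes. The difference between the tissues in the effect of low protein was tested in a limma fit of all 24 arrays with 8 tissue and diet means. In that fit the probe set of a gene was the one with the highest mean over the 24 arrays. Its values can therefore come from other probe sets than those of the fit of a single tissue. In the text "rose" and "fell" are used for called genes and log2 differences are given with the standard error of limma.

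Gene lists were tested with camera from limma, with its preset correlation of 0.01 between genes and, as an alternative, with a correlation estimated from the data. The preset makes p too small where the genes of a list vary together over the arrays. In the fit of both tissues the estimated correlation was 0.560 for complex I and 0.469 for fast fibre genes. It was 0.0701 for the IGF list. A list past camera with the preset alone therefore describes these arrays. Of 50 lists 49 had the minimum of 5 measured members in each tissue. Member counts are given over all genes and adjusted over the list alone. The groups, contrasts, gene lists, alternatives and the rule for genes named in the text were fixed before the data were examined. By that rule the text names genes from the 8 largest rises and 8 largest falls among called genes for LP against NP, and from the 5 and 5 largest for other contrasts, provided that the 3 values of a group lie on one side of those of the other. Where fewer passed, the genes with the smallest p are given as values. The rule adds up to 3 genes of each list past camera, and Slc6a6, Csad, Cdo1, Ppargc1a, Pdk4, Cpt1a, Asns, Igf1, Igf2 and Igfbp1 in LP against NP and LPtau against LP. Symbols that are only clone or predicted gene names were not named.

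The contrasts of LP with NP and of LPtau with LP share the LP arrays, and those of LP with NP and of LPtau with NP share the NP arrays. Chance therefore links their differences. The linked measures were set against 100 simulations of unchanged groups that share arrays in the same way. The simulations gave every diet the same spread, as did the subtraction described next. The slope of LPtau minus NP on LP minus NP across genes was computed after subtracting from its covariance and variance the part that the residual variance gives. The subtraction first used limma's moderated variances. It was changed to residual variances after both slopes had been seen, because simulated data with a known slope showed the moderated form to be biased. For true slopes of 0, 0.5 and 1 the mean over 10 simulations was 0.0061, 0.505 and 1.00 in liver and -0.0059, 0.497 and 1.00 in muscle with residual variances, and 0.0461, 0.505 and 0.964 in liver and 0.0608, 0.498 and 0.935 in muscle with moderated ones.

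The alternatives were the mean of all probe sets of a gene, only genes above the median level, cyclic loess normalization, eBayes with trend and robust set, limma's array weights, only the arrays of the groups compared, the replicate number as a block, the sex of the pups by Xist and Y-linked genes as a covariate, the mean of the erythroid genes as a covariate in liver, and each array left out in turn. Other splits of the arrays were counted for each limma result, with all 10 splits of 6 arrays or 100 draws. The fits were tested on simulated data with 18193 genes and the spread of the real ones, of which 50 each were changed by 0.5, 1, 2 and 3. For LP against NP limma recovered 14%, 66%, 100% and 100% in liver and 10%, 64%, 88% and 98% in muscle. For LPtau against LP it recovered 36%, 74%, 92% and 100% in liver and 6%, 56%, 90% and 96% in muscle. For the interaction it recovered 2%, 56%, 80% and 98% in liver and 2%, 38%, 82% and 96% in muscle, and for the difference between the tissues 2%, 50%, 90% and 92%.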

Results

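Messenger RNA was measured with Affymetrix oligonucleotide arrays in liver and in hindleg skeletal muscle of newborn mice on the day of birth. The mothers received 1 of 4 diets from day 1 of pregnancy. The normal protein diet (NP) held 20% casein and the low protein diet (LP) 8%. Each diet was given with plain water or with 1% taurine in the drinking water (NPtau and LPtau). Taurine is a sulfur-containing amino acid derivative that a fetus obtains largely from its mother. Each of the 8 tissue and diet groups held 3 arrays, 24 in all, and the number of arrays limits the precision. The median log2 value of an array was 5.35 to 5.39 in liver and 4.95 to 5.04 in muscle. The labels call the arrays biological replicates but do not state whether the pups of a group came from separate dams or litters, so the p-values measure the spread between these samples. By the level of Xist and of Y-linked genes, 12 arrays came from females and 12 from males. In each tissue 2 of 3 LP and 2 of 3 NPtau arrays were female, against 1 of 3 NP and 1 of 3 LPtau arrays.

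The effect of low protein on the newborn liver was measured as LP against NP. Sult2a2, a sulfotransferase of bile acids and steroids, rose by 4.43 (log2, SE 0.69, n = 3 per group; adjusted p = 0.0172 with limma). Gstt3, a glutathione transferase, rose by 2.90 (SE 0.36), and Gpt, the alanine aminotransferase that passes nitrogen from alanine into the urea pathway, rose by 2.24 (SE 0.23; adjusted p = 0.00376 with limma). Hal, which breaks down histidine, rose by 1.54 (SE 0.16). Dusp9, a phosphatase that switches off MAP kinases, rose by 2.49 (SE 0.26), and S100g, a vitamin D dependent calcium-binding protein, rose by 2.37 (SE 0.41). Cyp2f2, a cytochrome P450, the ubiquitin ligase adaptor Klhl13 and the kinase Sgk2 rose by 2.46 (SE 0.49), 2.34 (SE 0.36) and 2.24 (SE 0.46). Rab30, a small GTPase of the Golgi, had the largest fall among the called genes and fell by 3.23 (SE 0.52; adjusted p = 0.0175 with limma). Mbl2, a mannose-binding lectin of blood plasma, fell by 2.81 (SE 0.51), and Crem, a transcription factor of cAMP signalling, fell by 2.62 (SE 0.54). Akr1c6, a reductase of steroids, and the sulfotransferase Sult3a1 fell by 2.45 (SE 0.40) and 2.46 (SE 0.34). Car3, a carbonic anhydrase, fell by 2.47 (SE 0.47) on the probe set used, while only 2 of its 4 probe sets had that sign. With limma 425 of 18193 genes passed an adjusted p of 0.05, 202 higher and 223 lower in LP, and 4125 had an unadjusted p under 0.05. In each of the 425 genes the 3 LP values lay all above or all below the 3 NP values. Over all genes this held for 29.2%, where chance gives 10%.

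**Figure D1:**
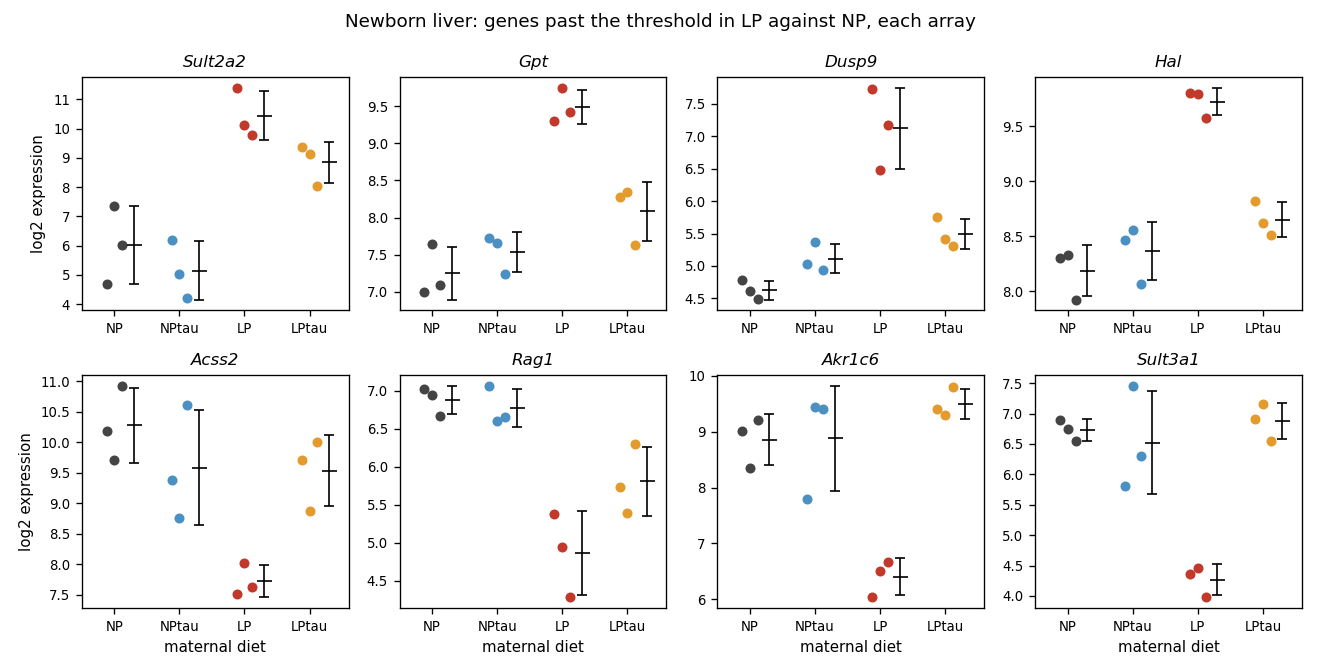
Log2 expression of 8 liver genes by maternal diet, with a point per array and a bar at the mean with the SD of 3 arrays. Sult2a2, Gpt, Dusp9 and Hal were higher in LP than in NP, and Acss2, Rag1, Akr1c6 and Sult3a1 were lower.

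Genes of complexes I, II and III of the mitochondrial respiratory chain were higher in LP liver. Of 34 genes of complex I, which feeds electrons from NADH into the chain, 33 had a positive difference (median 0.32). Ndufv2 rose by 0.56 (SE 0.12), 33 complex I genes did not pass over all genes, and 11 rose adjusted over the list alone. The complex I list passed camera at an adjusted p = 1.03e-07, and had an adjusted p = 0.555 with an estimated correlation. Of 15 genes of complexes II and III (median 0.37) 0 passed over all genes, 11 rose adjusted over the list alone, and camera gave an adjusted p = 1.60e-05 (adjusted p = 0.555 with an estimated correlation). Among 76 genes of the mitochondrial ribosome (median 0.19) Mrps35 rose by 0.75 (SE 0.12), Mrpl20 rose by 0.60 (SE 0.12), 74 did not pass and 4 rose adjusted over the list alone. Of 21 complex IV genes 13 were positive (median 0.07), and that list was not called (adjusted p = 0.273 with camera). Atp5a1 of the ATP synthase rose by 0.49 (SE 0.09), with 2 of its 3 probe sets of that sign. Genes of fatty acid and triglyceride synthesis were lower. Of 22 such genes 3 fell and 19 did not pass, and 7 fell adjusted over the list alone. Acss2, which makes acetyl-CoA from acetate, fell by 2.56 (SE 0.45) on the probe set used, with 2 of its 3 probe sets of that sign. Fads2, a fatty acid desaturase, fell by 1.70 (SE 0.36), and Me1, the malic enzyme that supplies NADPH, fell by 1.40 (SE 0.27). The list had a median of -0.21, a mean of -0.58 (SE 0.27) and an adjusted p = 0.00239 with camera (adjusted p = 0.555 with an estimated correlation). In the list of gluconeogenesis and amino acid breakdown, 3 of 16 genes rose (Gpt, Hal and Prodh), 1 fell (Fbp1) and 12 did not pass, and camera gave an adjusted p = 0.593, so the list as a whole was not called. Its median was -0.02 and its mean 0.18. Prodh, which breaks down proline, rose by 1.20 (SE 0.19). Fbp1, an enzyme of glucose synthesis, fell by 0.55 (SE 0.11). Prodh, Fbp1 and the LP value of Hal were chosen after their values were seen.

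Markers of lymphocytes, granulocytes, erythroid cells and vessel cells and genes of cell division were lower in LP liver. The macrophage and megakaryocyte lists had smaller liver medians, at -0.149 and -0.0426 in the fit of both tissues. Of 18 lymphocyte genes 4 fell and 14 did not pass, and 9 fell and 1 rose adjusted over the list alone. Rag1, the recombinase of antigen receptor genes, fell by 2.01 (SE 0.28), the B cell factor Ebf1 fell by 1.90 (SE 0.29) with 4 of its 5 probe sets of that sign, and the B cell receptor chain Cd79b fell by 1.55 (SE 0.33). Pou2af1, a B cell coactivator outside that list, fell by 2.87 (SE 0.54). The lymphocyte list had a median of -0.68 and an adjusted p = 0.000210 with camera (adjusted p = 0.555 with an estimated correlation). Of 18 endothelial genes 4 fell and 14 did not pass, and 6 fell adjusted over the list alone. Esam and Pecam1, adhesion proteins of vessel walls, fell by 1.07 (SE 0.18) and 0.80 (SE 0.14). Cdh5, the cadherin of vessels, fell by 1.11 (SE 0.22) with 1 of its 2 probe sets of that sign. The endothelial list passed camera at an adjusted p = 5.46e-05 (adjusted p = 0.555 with an estimated correlation). Of 38 cell cycle genes 37 had a negative difference (median -0.54). Ccne2, a cyclin of the start of DNA replication, fell by 1.59 (SE 0.20; adjusted p = 0.00786 with limma), 37 did not pass and 2 fell adjusted over the list alone. Camera gave the cell cycle list an adjusted p = 1.98e-10 (adjusted p = 0.555 with an estimated correlation). The erythroid list (26 genes, median -0.27) was also lower at an adjusted p = 0.00752 with camera (adjusted p = 0.687 with an estimated correlation), although its single called gene, Car1, rose by 2.08 (SE 0.33). The mean of the erythroid list in liver, relative to NP, was -0.59, -0.23 and 0.02 in LP replicates 1, 2 and 3. Car1 was chosen after its value was seen. Of 19 interferon response genes (median -0.56) and of 16 granulocyte genes (median -0.57) 0 passed over all genes with limma, and 3 and 6 fell adjusted over the list alone. Of 49 lists 21 passed camera, 5 higher and 16 lower, and 0 with an estimated correlation. Without LP replicate 1 it was 10, 3 higher and 7 lower.

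Igf1, the growth factor that the liver releases into blood, had a difference of -1.02 (SE 0.31, adjusted p = 0.103 with limma) with all 3 LP values below the NP values. The taurine transporter Slc6a6 had a difference of 0.68 (SE 0.30) and the taurine synthesis genes Csad and Cdo1 had -0.44 (SE 0.16) and -0.54 (SE 0.29), and none of these 3 passed. Pdk4, Cpt1a, Asns, Ppargc1a, Igf2 and Igfbp1 did not pass either. The count of 425 liver genes was 21, 181 and 48 without NP replicates 1, 2 and 3, and 2013, 30 and 29 without LP replicates 1, 2 and 3. With the sex of the pups as a covariate it was 234, of which 220 were among the 425.

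The effect of taurine under low protein was measured in liver as LPtau against LP. Akr1c6 rose by 3.10 (SE 0.40, n = 3 per group; adjusted p = 0.0401 with limma), Sult3a1 rose by 2.61 (SE 0.34) and Cyp2j5, a P450 that oxidises arachidonic acid, rose by 1.99 (SE 0.30). Klf10, a transcription factor induced by TGF-beta, rose by 1.72 (SE 0.24), and Serpina7, the thyroxine-binding globulin of plasma, rose by 1.47 (SE 0.22). Hal fell by 1.07 (SE 0.16), the membrane transporter Slc23a3 fell by 1.36 (SE 0.19) and the phosphodiesterase Pde6c fell by 1.14 (SE 0.16). These 8 were among 12 genes that passed with limma, 9 higher and 3 lower in LPtau, with all 3 LPtau values on the same side of the 3 LP values. An unadjusted p under 0.05 was found for 1543 genes.

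Collagens and other matrix genes were higher in LPtau than in LP liver. Of 25 genes of extracellular matrix and fibroblasts 24 had a positive difference (median 0.81, mean 0.80, SE 0.28). With limma 0 passed over all genes and 19 rose adjusted over the list alone. Postn, a matrix protein of tissue growth and repair, had a difference of 1.13 (SE 0.20), and the collagen gene Col5a2 had 1.02 (SE 0.25). Camera gave the matrix list an adjusted p = 1.38e-17 (adjusted p = 0.281 with an estimated correlation). Markers of cells that make matrix moved with it in liver. All 14 genes of stellate and mesothelial cells were positive (median 0.47), with a list mean relative to NP of -0.53 to -0.33 in LP and -0.16 to 0.40 in LPtau (camera adjusted p = 4.23e-06, and adjusted p = 0.281 with an estimated correlation). Of 13 genes of smooth muscle and pericytes 12 were positive (median 0.57), with a list mean of -0.61 to -0.29 in LP and -0.05 to 0.38 in LPtau (camera adjusted p = 4.23e-06, and adjusted p = 0.384 with an estimated correlation). Of the stellate list 6 genes and of the smooth muscle list 2 genes are also in another list, and 10 and 7 lay above the median level in NP liver. Of 22 genes of fatty acid and triglyceride synthesis (median 0.49) 0 passed over all genes with limma and 7 rose adjusted over the list alone, with Fads2 at 1.64 (SE 0.36) and Me1 at 1.24 (SE 0.27). That list had an adjusted p = 4.23e-06 with camera (adjusted p = 0.290 with an estimated correlation). Of 18 endothelial genes (median 0.31) 0 passed over all genes and 6 rose adjusted over the list alone, with Pecam1 at 0.81 (SE 0.14). Of 34 complex I genes 30 had a negative difference (median -0.14) and 0 passed in either count. Igf1 had a difference of 1.25 (SE 0.31, adjusted p = 0.245 with limma), and Csad and Slc6a6, at 0.63 (SE 0.16) and -0.50 (SE 0.30), did not pass. Of 49 lists 25 passed camera, 19 higher and 6 lower, and 0 with an estimated correlation. Without LP replicate 1 it was 15, 13 higher and 2 lower.

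All 12 genes were also among the 425 of LP against NP, with the opposite sign, where independent lists would share 0.280. Both comparisons use the LP arrays, so chance alone gives them opposite signs. Of the 425 genes 417 (98.1%) had the opposite sign in LPtau against LP. Among as many simulated unchanged genes, picked for the largest difference for their spread, the share was 93.2%. The median size of the 425 differences was 0.88 in LP against NP and 0.40 in LPtau against NP, and the median ratio of the latter to the former was 0.452, against 0.498 in the simulated genes. Of the 425 genes 0 passed with limma in LPtau against NP. Across all genes the covariance of LP minus NP with LPtau minus NP was 0.0604, against 0.0245 in simulated groups without effects. The slope of LPtau minus NP on LP minus NP, after removing the part that the spread of the arrays gives, was 0.373. A slope of 1 would mean that the low protein differences were as large with taurine as without, and a slope of 0 that none remained. The slope ran from 0.248 without LPtau replicate 2 to 0.585 without LPtau replicate 3. The direct test, whether the effect of low protein differed with and without taurine, called 0 genes with limma (1540 at an unadjusted p under 0.05, smallest adjusted p = 0.201). The count of 12 was 269, 1 and 0 without LP replicates 1, 2 and 3, and 1, 0 and 0 without LPtau replicates 1, 2 and 3. It was 0 with the sex covariate and 0 with cyclic loess normalization.

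**Figure D2:**
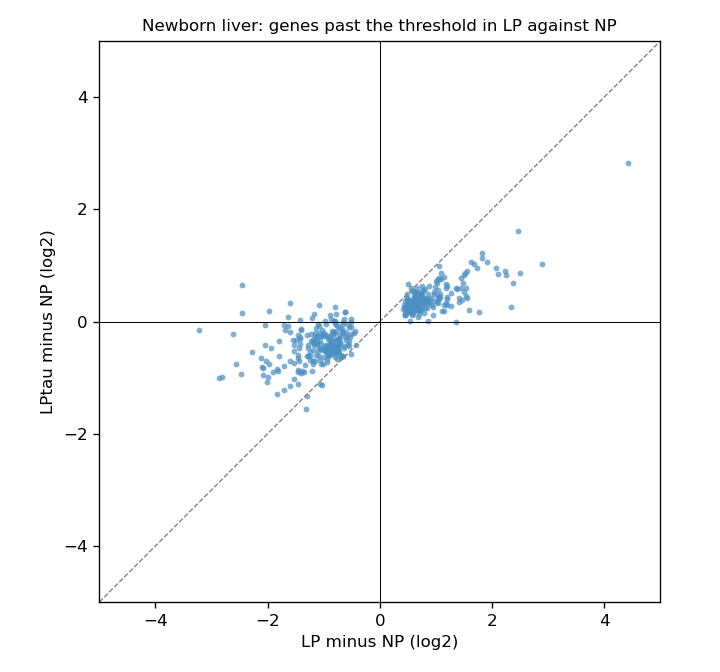
Difference from NP in LP (horizontal) and in LPtau (vertical), log2, for the 425 liver genes called in LP against NP, with a dashed line where both are equal. For 417 of the 425 genes the LPtau mean lay nearer to NP than the LP mean did.

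The effect of taurine under normal protein on the liver was measured as NPtau against NP. With limma 0 genes passed (500 at an unadjusted p under 0.05). The lowest p-values belonged to genes such as Osbpl3, a lipid transfer protein, at -0.47 (SE 0.10), and Adamts5, a matrix protease, at 0.57 (SE 0.15). Sgk1, a kinase induced by glucocorticoids, had a difference of -0.93 (SE 0.29) with all 3 NPtau values below the NP values. Relative to NP it also stood at -1.40 in LP and -0.91 in LPtau, so the lower level was not particular to NPtau. Sgk1 belongs to the glucocorticoid and FOXO list of 25 genes (22 negative, median -0.27), which had an adjusted p = 1.08e-06 with camera (adjusted p = 0.934 with an estimated correlation). In that list 0 genes passed in either count.

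What separated the livers of low protein pups with taurine from control livers was measured as LPtau against NP. With limma 0 genes passed (1231 at an unadjusted p under 0.05). Ccne2 had a difference of -1.15 (SE 0.20), and the axon guidance receptor Robo1 had -1.12 (SE 0.18), both with all 3 LPtau values below the NP values. The cell cycle list (38 genes, 34 negative, median -0.28) was lower at an adjusted p = 3.89e-07 with camera (adjusted p = 0.926 with an estimated correlation), and 1 of its genes fell adjusted over the list alone. Its mean in liver, relative to NP, was -0.34, -0.64 and 0.17 in LPtau replicates 1, 2 and 3, and the erythroid list moved with it, at -0.38, -0.68 and 0.09. The complex I list (33 of 34 positive, median 0.20) was higher at an adjusted p = 1.94e-05 with camera (adjusted p = 0.926 with an estimated correlation).

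The effect of low protein on newborn hindleg muscle was measured as LP against NP. Mybpc2, the fast form of myosin-binding protein C, fell by 4.50 (log2, SE 0.40, n = 3 per group; adjusted p = 0.00228 with limma), and Pvalb, parvalbumin, the calcium buffer of fast fibres, fell by 4.14 (SE 0.32; adjusted p = 0.000987 with limma). Actn3, the actinin of fast fibres, fell by 2.98 (SE 0.37), and Abra, an activator of actin-dependent transcription, fell by 3.64 (SE 0.52). Cox7a1, the muscle form of a complex IV subunit, fell by 2.27 (SE 0.28), and Eef1a2, the translation factor of mature muscle, fell by 2.25 (SE 0.32). The muscle gene Asb11 and the potassium channel gene Kcna5 fell by 1.93 (SE 0.28) and 1.84 (SE 0.26). Gli1, the transcription factor that reports hedgehog signalling, rose by 1.496 (SE 0.19; adjusted p = 0.0213 with limma). Mylip, a ubiquitin ligase for the LDL receptor, rose by 0.76 (SE 0.10), and the RNA processing genes Cpsf6 and Mbnl3 rose by 0.75 (SE 0.11) and 0.66 (SE 0.10), with 5 of 6 probe sets of Cpsf6 of that sign. With limma 23 of 18193 genes passed, 4 higher and 19 lower in LP, and 1957 had an unadjusted p under 0.05. In each of the 23 genes the 3 LP values lay all above or all below the 3 NP values. Over all genes this held for 19.6%, where chance gives 10%.

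**Figure D3:**
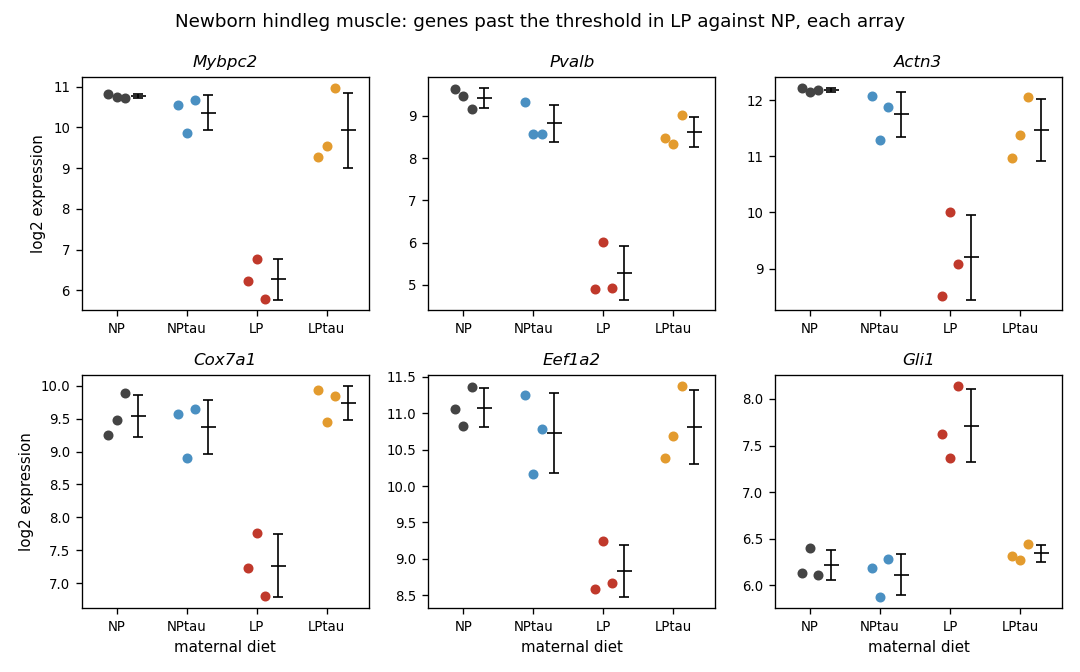
Log2 expression of 6 muscle genes by maternal diet, with a point per array and a bar at the mean with the SD of 3 arrays. Mybpc2, Pvalb, Actn3, Cox7a1 and Eef1a2 were lower in LP than in NP, and Gli1 was higher.

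All 21 measured fast fibre genes had a negative difference in LP muscle (median -0.81, mean -1.26, SE 0.23). Over all genes 3 fell and 18 did not pass, and 15 fell adjusted over the list alone. Camera gave the list an adjusted p = 1.62e-18 (adjusted p = 0.402 with an estimated correlation). The mean of the list, relative to NP, was -1.68, -0.88 and -1.22 in the 3 LP arrays and -0.06 to 0.04 in the NP arrays. Genes of energy metabolism were lower too. All 34 complex I genes had a negative difference (median -0.51), 0 passed over all genes with limma and 15 fell adjusted over the list alone (camera adjusted p = 3.39e-17, and adjusted p = 0.402 with an estimated correlation). Ndufb10 had the lowest p of that list, with a difference of -0.89 (SE 0.18). All 17 genes of the TCA cycle and pyruvate dehydrogenase were negative (median -0.62), and 9 fell adjusted over the list alone. Of 76 genes of the mitochondrial ribosome 74 were negative (median -0.37), and 8 fell adjusted over the list alone. Of 30 genes of fatty acid oxidation (median -0.62) 4 fell adjusted over the list alone, and Pdk4, which turns muscle from glucose to fat, had a difference of -3.02 (SE 0.62, adjusted p = 0.0930 with limma). These 3 lists passed camera and had an adjusted p = 0.402 with an estimated correlation. Markers of other cells moved with these lists in muscle. All 14 adipocyte genes were negative (median -0.75), with a list mean relative to NP of -1.02 to -0.44 in LP and -0.29 to 0.43 in NP (camera adjusted p = 0.0189, and adjusted p = 0.694 with an estimated correlation), and 10 of the 14 lay above the median level in NP muscle. Of 18 endothelial genes 17 were negative (median -0.41), with a list mean of -0.71 to -0.31 in LP and -0.06 to 0.06 in NP (camera adjusted p = 3.26e-06, and adjusted p = 0.402 with an estimated correlation). Slow fibre genes (15, median -0.41, 2 fell adjusted over the list alone) and embryonic and neonatal muscle genes (14, median -0.22, 1 fell adjusted over the list alone) each had an adjusted p = 0.00988 with camera (adjusted p = 0.694 and adjusted p = 0.712 with an estimated correlation). The embryonic list mean in muscle was -0.93 in LP replicate 1 and -0.11 and -0.08 in the other LP arrays. Genes of the cytosolic ribosome (43, of which 37 positive, median 0.14) were higher at an adjusted p = 1.50e-05 with camera (adjusted p = 0.565 with an estimated correlation), and 0 passed in either count. Slc6a6 had a difference of 0.55 (SE 0.19), and Igf1 and Igf2 had -0.20 (SE 0.23) and -0.10 (SE 0.13), none past the threshold.

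Markers of other tissues varied between the muscle arrays. Keratinocyte genes, relative to NP, stood at 4.45 in LP replicate 1 and at -0.42 and -0.48 in the other LP arrays. Of their list of 20 genes 10 lay above the median level in NP muscle. Genes of cartilage and bone stood at 2.08, 2.68 and -0.65 in the LP arrays and at 1.80, 1.36 and 1.81 in the LPtau arrays, against -0.75 to 0.61 in NP. Genes of hepatocytes stood at 1.87 in LP replicate 3. The signal of beta-actin from its 3 prime end exceeded that from its 5 prime end by 0.28 to 0.47 in the LP arrays and by 0.16 to 0.28 in the NP arrays, with all 3 LP values above the NP values. For pyruvate carboxylase this excess was 1.02 to 1.42 in LP and 1.51 to 2.24 in NP, with all 3 LP values below the NP values. For Gapdh and the transferrin receptor the values of LP and NP overlapped. The count of 23 muscle genes was 3, 2 and 2 without NP replicates 1, 2 and 3, and 49, 126 and 12 without LP replicates 1, 2 and 3. It was 5 with the sex covariate. Mybpc2 and Pvalb stayed past the threshold in all 15 settings with a value for them.

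The effect of taurine under low protein was measured in muscle as LPtau against LP. Mybpc2 rose by 3.66 (SE 0.40, n = 3 per group; adjusted p = 0.0143 with limma), Pvalb rose by 3.33 (SE 0.32; adjusted p = 0.00913 with limma) and Cox7a1 rose by 2.47 (SE 0.28), while Mylip fell by 0.83 (SE 0.10). With limma these were the 4 genes past the threshold, 3 higher and 1 lower in LPtau, and 2345 had an unadjusted p under 0.05. Actn3 had a difference of 2.26 (SE 0.37, adjusted p = 0.0836 with limma) and Gli1 had -1.37 (SE 0.19, adjusted p = 0.0522 with limma), each with all 3 LPtau values on the same side of the LP values. All 21 fast fibre genes had a positive difference (median 0.63, mean 1.00, SE 0.30), 2 rose over all genes and 19 did not pass, and 10 rose adjusted over the list alone (camera adjusted p = 3.81e-12, and adjusted p = 0.737 with an estimated correlation). All 34 complex I genes were positive (median 0.52), 0 passed over all genes with limma and 15 rose adjusted over the list alone (camera adjusted p = 1.14e-16, and adjusted p = 0.737 with an estimated correlation). Of 16 ATP synthase genes (median 0.48) 8 rose adjusted over the list alone, as did 9 of 21 complex IV genes (median 0.44). The excess of the 3 prime over the 5 prime signal of beta-actin moved with these lists, at 0.118 to 0.174 in the LPtau arrays and 0.278 to 0.468 in the LP arrays. That of pyruvate carboxylase overlapped, at 0.64 to 2.00 in LPtau and 1.02 to 1.42 in LP.

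**Figure D4:**
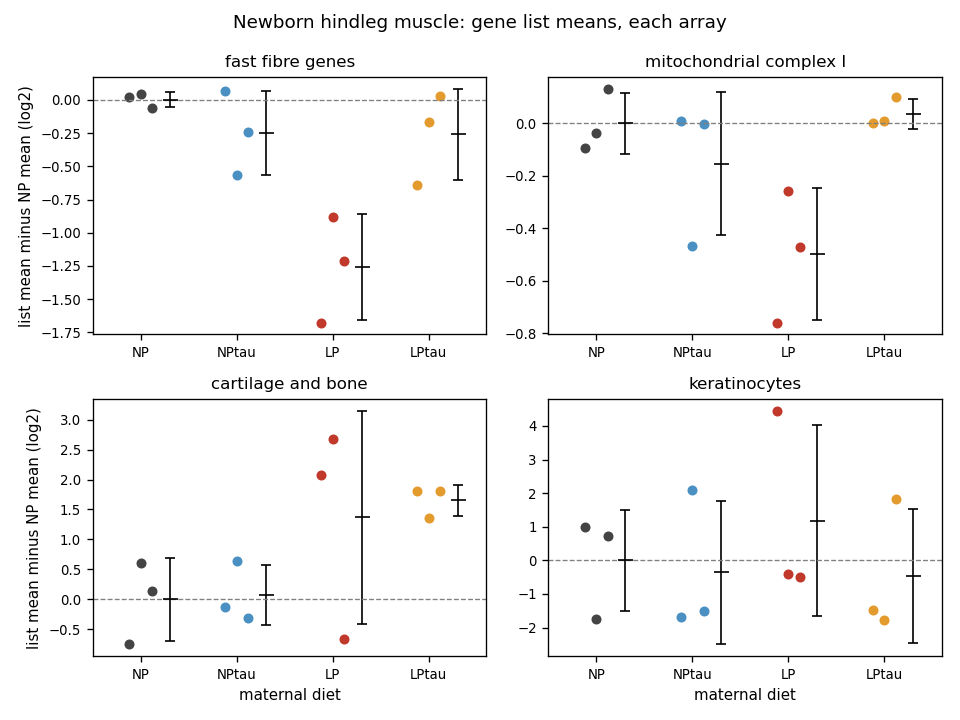
Mean log2 level of 4 gene lists in each muscle array, relative to the NP mean, by maternal diet. The fast fibre mean was -1.68, -0.88 and -1.22 in LP and -0.64, -0.17 and 0.03 in LPtau, and the keratinocyte mean was 4.45 in LP replicate 1.

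All 4 genes were among the 23 of LP against NP, with the opposite sign, where independent lists would share 0.00510. All 23 genes had the opposite sign in LPtau against LP, and simulated unchanged genes picked for their large difference gave 97.1%. The median size of the 23 differences was 1.17 in LP against NP and 0.27 in LPtau against NP, and the median ratio of the latter to the former was 0.196, against 0.503 in the simulated genes. Of the 23 genes 0 passed with limma in LPtau against NP. The covariance across all genes of LP minus NP with LPtau minus NP was 0.0330, below the 0.0396 of simulated groups without effects, and the slope with the spread of the arrays removed was -0.151. The slope was -0.634, -1.18 and -1.48 without NP replicates 1, 2 and 3, 0.150 without LP replicate 1, and -0.185 to -0.0582 without each other array. With limma's moderated variances in place of the residual ones it was 0.0158, so its sign is not settled. The simulations and the subtraction gave every diet the same spread, while the part shared here comes from the NP arrays alone. The muscle covariance of LP minus NP with NPtau minus NP was 0.0107, against 0.0396 simulated. The simulated values and the subtraction may therefore not hold for these arrays, so neither ratio nor slope shows a return to NP beyond chance. The direct test for a different effect of low protein with and without taurine called 0 genes with limma (1194 at an unadjusted p under 0.05), and its smallest adjusted p was 0.0544. The count of 4 was 14, 75 and 0 without LP replicates 1, 2 and 3, and 9 and 2 without LPtau replicates 1 and 3. It was 0 when only the arrays of LPtau and LP were fitted.

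The effect of taurine under normal protein on muscle was measured as NPtau against NP. With limma 0 genes passed (88 at an unadjusted p under 0.05). All 10 hepatocyte genes had a positive difference (median 0.58), with Alb, serum albumin, at 1.81 (SE 0.87) and Fga, a fibrinogen chain, at 1.30 (SE 0.56). That list had an adjusted p = 4.50e-07 with camera (adjusted p = 0.900 with an estimated correlation), and 1 of its 10 genes lay above the median level in NP muscle. Genes of the cytosolic ribosome (40 of 43 negative, median -0.13) were lower at an adjusted p = 2.20e-09 with camera (adjusted p = 0.900 with an estimated correlation). Their mean in muscle, relative to NP, was -0.30 in NPtau replicate 2 and -0.03 in each of the other NPtau arrays. NPtau replicate 2 stood apart in this group, with a fast fibre mean of -0.57 and a complex I mean of -0.47 relative to NP.

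What separated the muscle of low protein pups with taurine from control muscle was measured as LPtau against NP. With limma 0 genes passed (682 at an unadjusted p under 0.05). Pvalb and Mybpc2 had differences of -0.81 (SE 0.32) and -0.83 (SE 0.40), and the fast fibre list (18 of 21 negative, median -0.16) was lower at an adjusted p = 0.0180 with camera (adjusted p = 0.847 with an estimated correlation). The mean of that list in muscle was -0.64, -0.17 and 0.03 in LPtau replicates 1, 2 and 3, relative to NP. Of 18 endothelial genes 16 were negative (median -0.54; camera adjusted p = 6.02e-07, and adjusted p = 0.841 with an estimated correlation), and 0 passed in either count.

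The effect of low protein was compared between the 2 tissues. No gene was called in both, where independent lists would share 0.537, so the calls neither overlapped nor avoided each other beyond chance. Across genes, which are not independent replicates, the LP minus NP differences of liver and muscle had a Pearson correlation of 0.0612 and a Spearman correlation of 0.0034. Of the 425 liver genes 202 (47.5%) had the same sign in muscle. A fit of all 24 arrays called 359 genes whose change differed between the tissues, 134 higher and 225 lower in muscle than in liver, and 3105 had an unadjusted p under 0.05. Mybpc2 had the most negative difference of the changes among the named genes, at -4.42, followed by Sult2a2 at -4.35. The complex I list was higher in LP liver and lower in LP muscle, with a median difference of -0.86 between the tissues (camera adjusted p = 1.13e-20, and adjusted p = 0.265 with an estimated correlation). The count of 359 was 119 and 192 without liver NP replicates 1 and 3, and 762, 128 and 152 without liver LP replicates 1, 2 and 3. It was 181, 193 and 133 without muscle NP replicates 1, 2 and 3, and 207 and 227 without muscle LP replicates 1 and 3. With only genes above the median level in both tissues it was 178.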

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

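The tests between tissues and the other splits of the arrays were planned, and the splits that move both tissues together and the tests of muscle share, sex, LP replicate 1, erythroid cells and array sharing below were chosen only after the results were seen. The results of the first 3 paragraphs were taken up because a limma test of the difference itself separated the effect of low protein in muscle from that in liver. The joint fit called 359 genes, and 1 of 100 drawn splits of the arrays, the real one, gave as many, with 308 the highest of the others. The draws moved the diet labels within each tissue. They therefore test whether low protein had any effect, not whether its effect differed between the tissues. Even if the tissues came from different pups, they do not exclude chance for that difference. If 1 pup gave both tissues, the labels move together, which leaves 10 splits, too few for a share under 5%. The real count was then 359 and the highest other 1. The 8 draws that kept the liver arrays split by diet gave up to 308 and the 91 others up to 76, so much of this count is the liver's own effect. Among 154 genes named for either tissue 47 differed, 15 with a higher and 32 with a lower change in muscle. A gene that is hardly expressed in 1 tissue may not be able to change there. Above the median level in NP lay 4 of 21 fast fibre genes in liver and 1 of 18 lymphocyte genes in muscle. Of 34 complex I genes 33 lay above it in each tissue. With only genes above the median level in both tissues 178 were called in place of 359.

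Values are the LP minus NP change in muscle less that in liver, log2. Among muscle genes Mybpc2 differed by -4.42, Pvalb by -4.35, Abra by -3.70, Actn3 by -3.30, Ankrd2 by -2.86, Cox7a1 by -2.37, Eef1a2 by -2.20, Kcna5 by -1.96 and Asb11 by -1.78. Among genes that rose in LP liver, Sult2a2 differed by -4.35, Gpt by -2.83, Gstt3 by -2.74, S100g by -2.44, Cyp2f2 by -2.43, Sgk2 by -2.05 and Klhl13 by -2.04. The metallothionein Mt1 differed by -1.48. Among mitochondrial genes Mrpl42 differed by -1.63, Atp5g1 by -1.54, Mrps36 by -1.44, Ndufb10 by -1.43, Uqcr11 by -1.39, Sdhb by -1.38, Mrps35 by -1.27, Dlat by -1.12, Pdhb by -1.11, Ndufs5 by -1.09, Idh3b by -1.05, Ndufv2 by -1.02, Ndufs4 by -0.995, Ndufa6 by -0.86 and Mrpl12 by -0.81. Among genes that fell in LP liver, Rab30 differed by 3.06, Mbl2 by 2.85, Pou2af1 by 2.82, the transcription factor Tcf4 by 2.62, Nupr1 by 2.62, Sult3a1 by 2.44, Akr1c6 by 2.37, Ebf1 by 2.33, Rag1 by 1.87, Cd79b by 1.62 and Colec11 by 1.22. The leptin receptor Lepr differed by 3.71, Gli1 by 1.32, Mbnl3 by 1.20 and the replication gene Mcm2 by 0.90.

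Camera separated 18 lists between the tissues and 0 of them with an estimated correlation, where the smallest adjusted p was 0.265. Medians were lower in muscle for complex I (-0.86), complexes II and III (-0.89), complex IV (-0.47), ATP synthase (-0.63), the mitochondrial ribosome (-0.55), the TCA cycle (-0.93), fatty acid oxidation (-0.66) and fast fibre genes (-0.96). They were higher in muscle for the IGF axis (0.18), hypoxia response (0.42), cell cycle (0.41), acute phase proteins (0.38), granulocytes (0.58), lymphocytes (0.59), stellate cells (0.59), extracellular matrix (0.47), cartilage and bone (1.07) and hepatocyte genes (0.63).

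Probe sets with no symbol or several lie outside the comparisons above and also carried a signal. Of 10092 such probe sets limma called 28 in LP against NP liver, 7 higher and 21 lower (1924 at an unadjusted p under 0.05), and 4 in muscle, all higher (906 at an unadjusted p under 0.05).

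Fast fibre and mitochondrial genes were lower in LP muscle, and a smaller share of muscle tissue in the LP samples was weighed as a technical explanation. It would lower other muscle genes alike, but the mean of the 21 fast fibre genes fell below that of 48 other muscle genes by -0.957 (SE 0.0661), with no overlap of LP and NP arrays, which excludes it as the whole cause for fast fibre genes. For 162 mitochondrial genes the same difference was -0.111 (SE 0.153), which leaves a smaller share open, but the other muscle genes stood at -0.76, -0.01 and -0.13 in LP replicates 1, 2 and 3 and the difference at 0.12, -0.16 and -0.29, so this rests on LP replicate 1. The 3 prime less 5 prime signal of actin was 0.278 to 0.468 in the LP and 0.160 to 0.276 in the NP muscle arrays. That of pyruvate carboxylase went the other way, at 1.02 to 1.42 in LP and 1.51 to 2.24 in NP. Those of Gapdh and the transferrin receptor overlapped, and whether RNA quality contributed stays open. An effect of the diet on the muscle itself stays open as well, and cannot be told from one of dam or litter, which the labels do not give.

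The 425 genes of LP against NP liver may come from the sexes of the pups, from LP replicate 1 or from fewer erythroid cells, and each was weighed by how far the 425 changes shrank when it was removed. The median ratio of the change with the sex covariate to that without was 0.983 (quartiles 0.945 and 1.02), without LP replicate 1 it was 1.04 (quartiles 0.959 and 1.13), and with the erythroid covariate 0.960 (quartiles 0.909 and 1.01). The ratios exclude none of these explanations, because the 425 genes were picked for a large LP minus NP difference against their spread. Genes that vary with sex, LP replicate 1 or erythroid cells within a diet would seldom be among them. The ratios show only that the called changes hardly shrank. The sex covariate lowered the count to 234 and kept 220 of the 425 genes. Of the 10 splits of the 6 arrays the real one called 425 genes and the highest other 1, and 10 splits are too few for a share under 5%. A difference between dams or litters that the labels do not record stays open beside the diet.

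Genes changed by low protein were opposed in LPtau, which could come from the LP arrays shared by both contrasts if taurine changed nothing. The slope of LPtau minus NPtau on LP minus NP, 2 contrasts with no array in common, would then be near 1. In liver it was 0.260 (jackknife SE 0.264, 0.146 to 0.474 with 1 array left out). That argues against the explanation only if the LP minus NP differences are not themselves chance, which 10 splits are too few to exclude. It also requires that sex and litter did not lower the slope. The LP and NPtau livers were 2 females and 1 male each, and the NP and LPtau livers 1 female and 2 males. The sex imbalance thus has opposite signs in the 2 contrasts, and no slope was computed with the sex covariate. With that covariate LPtau against LP liver called 0 genes in place of 12. In muscle the slope was 0.542 (jackknife SE 0.719, 0.185 to 1.46 with 1 array left out), so there the 2 explanations cannot be told apart with this many arrays. The interaction called 0 genes with limma in both tissues (1540 and 1194 at an unadjusted p under 0.05), so no single gene was shown to respond to low protein differently with taurine.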

How the results depend on the processing

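The fits without the arrays that stood apart and the random block over the tissues were chosen after seeing the data, as was the residual variance behind the slopes in the text, which replaced the moderated one used first. The other alternatives were planned. Of 10426 values of named genes under the alternatives 9801 kept their side of the threshold, 327 lost the call, 298 gained one and 0 called values reversed. Many of these genes had no call to lose, so the total does not measure how stable the calls were. The losses included 155 in LP against NP liver, 66 in LPtau against LP liver and 72 in LP against NP muscle. In LPtau against LP liver the named called genes kept the call in 6 to 9 of their 15 or 16 settings. In LP against NP liver Ndufv2 kept it in 6 of 16 and Gpt in 16 of 16. Of 900 list values 698 kept theirs, 199 lost the call and 3 reversed. The median of all genes moved by under 0.1 with cyclic loess in the 4 comparisons of 2 diets in each tissue. The cause of the changes below was not tested.

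In liver, array weights called 4727 genes in LP against NP (425), 512 in LPtau against LP (12), 16 in LPtau against NP (0) and 5 in the interaction (0). The sex covariate called 234 and 0 in the first 2. Leaving out LP replicate 1 and NPtau replicate 2 together called 2914, 586, 2 and 18. For LPtau against LP the mean of probe sets called 20, genes above the median 7, cyclic loess 0, the erythroid covariate 30 and only the groups compared 7. For the interaction the mean of probe sets called 1 and the erythroid covariate 3. Genes called in LP against NP and opposite in LPtau against LP numbered 20 with the mean of probe sets and 7 above the median. Only the groups compared gave 315 genes in LP against NP, 34.6% of them higher, against 47.5%.

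In muscle, LP against NP (23 genes) gave 38 with the mean of probe sets, 36 above the median, 65 with cyclic loess, 789 with array weights, 5 with the sex covariate, 669 without LP replicate 1, LPtau replicate 1 and NPtau replicate 2, and 14 with only the groups compared. LPtau against LP (4) gave 13, 8, 67 and 281 in the first 4 of these, 10 with trend and robust, 97 without the arrays that stood apart and 0 with only the groups compared. The interaction (0) gave 2 above the median, 1 with cyclic loess, 1 with trend and robust and 4 with array weights. Opposite calls (4) gave 10 with the mean of probe sets and 8 above the median. The difference between the tissues (359) gave 178 above the median, 2736 with array weights and 1806 without the arrays that stood apart.

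With the replicate number as a block muscle gave 2 genes in LP against NP, 0 in LPtau against LP and 0 opposite calls, and the block changed no other count by over 1.5 times (liver 403 and 14, tissues 321). The numbers were not taken to pair the arrays, since only 6 of 18 same-numbered pairs in each tissue correlated over 0.1. In liver 8 of 12 arrays correlated best with their own number (mean 0.0543, other pairs -0.0279), a hint from the data and not the design, and in muscle 1 of 12 (mean -0.0361, other pairs 0.0191). Diet and number as a random block over both tissues called 485 genes between the tissues.

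Lists past camera with an estimated correlation numbered 0 in each of the 10 contrasts. In NPtau against NP liver (6 lists) the sex covariate left 1, and in LPtau against NP muscle (17 lists) the genes above the median left 11. The slopes with moderated variances were 0.383 in liver and 0.0158 in muscle.

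With each array left out in turn, LP against NP ran from 21 (without NP replicate 1) to 2013 (without LP replicate 1) genes in liver and from 2 (NP replicates 2 and 3) to 126 (LP replicate 2) in muscle. LPtau against LP ran from 0 (LP replicate 3, LPtau replicates 2 and 3) to 269 (LP replicate 1) in liver and from 0 (LP replicate 3) to 75 (LP replicate 2) in muscle. The interaction ran from 0 to 8 (LP replicate 1) in liver, with 4 without NPtau replicate 2, and from 0 to 5 (LP replicate 2) in muscle, with 1 each without NPtau replicate 1 and LPtau replicate 1. NPtau against NP and LPtau against NP stayed at 0 in both tissues. The difference between the tissues ran from 119 (liver NP replicate 1) to 762 (liver LP replicate 1). Opposite calls ran from 0 to 253 in liver and 0 to 64 in muscle, and slopes from 0.248 to 0.585 and from -1.48 to 0.150. Lists past camera in liver ran from 10 (LP replicate 1) to 23 in LP against NP, 15 (LP replicate 1) to 23 in LPtau against LP, 2 (NP replicate 3) to 15 (NP replicate 2) in NPtau against NP, 8 (NP replicate 3) to 19 in LPtau against NP and 14 to 22 in the interaction. In muscle they ran from 20 to 22, 14 to 21, 10 (NPtau replicate 2) to 25, 9 (LPtau replicate 1) to 18 and 11 to 20.

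Without LP replicate 1 the list median reversed for glucocorticoid and FOXO genes in LPtau against LP liver (-0.0441, range with each array left out -0.0441 to 0.382), and for keratinocyte genes in LP against NP muscle (-0.33, range -0.33 to 2.10) and in LPtau against LP muscle (0.0188, range -2.50 to 0.0188). The number of arrays limits the precision of every count. No background level was estimated, so what signal over background limits is known only from the fits above the median level.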

Other observations

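The tests below of muscle maturation, of erythroid cells and of pups shared by the tissues were chosen only after the result was seen. In muscle, target genes of ATF4, a factor that acts during amino acid shortage, were higher as a list in LPtau than in LP and in NP. Mthfd2, a mitochondrial enzyme of folate metabolism, had differences of 1.91 (log2, SE 0.40, n = 3 per group) against LP and 1.72 (SE 0.40) against NP. Phgdh, the entry enzyme of serine synthesis, had 0.66 (SE 0.16) against NP, Aldh18a1, an enzyme of proline synthesis, had 0.66 (SE 0.16) against NP, and Asns, the asparagine synthetase, had 1.52 (SE 0.38) against LP. Of 37 ATF4 target genes 29 were positive in each comparison, 0 passed over all genes with limma, and 5 and 4 rose adjusted over the list alone. The list passed camera at an adjusted p = 0.000708 against LP and 2.02e-06 against NP (adjusted p = 0.746 and adjusted p = 0.841 with an estimated correlation). The list mean in muscle, relative to NP, was 0.12, 0.58 and 0.18 in LPtau replicates 1, 2 and 3, and without LPtau replicate 2 the list did not pass camera against LP (median 0.0949).

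Cell cycle genes were lower in LPtau than in NP in muscle, with 34 of 38 negative (median -0.40, adjusted p = 4.42e-12 with camera, adjusted p = 0.841 with an estimated correlation) and 0 past the threshold in either count. The cell cycle mean in muscle was -0.77 in LPtau replicate 1 and -0.19 and -0.15 in the other LPtau arrays. Genes of cartilage matrix were higher in LPtau than in NP muscle, with 19 of 19 positive (median 1.59, adjusted p = 3.47e-09 with camera, adjusted p = 0.841 with an estimated correlation), and 8 of the 19 lay above the median level in NP muscle. Matn3, a matrix protein of cartilage, had a difference of 2.26 (SE 0.66) and Hapln1, which links proteoglycans to hyaluronan, had 2.54 (SE 0.76), neither past the threshold with limma.

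A delay of muscle maturation under low protein is a candidate explanation for the lower fast fibre genes, and was tested with 5 pairs of a mature and an early form of the same protein. The mature form less the early one, averaged over the pairs, was -1.27 (SE 0.175) in LP relative to NP, at -1.44 to -0.97 in the LP arrays, -0.17 to 0.12 in the NP arrays and -0.08 to 0.33 in the LPtau arrays. In LP, Cox7a1 less Cox7a2 stood at -1.88, Eef1a2 less Eef1a1 at -2.43 and Myh4 less Myh3 at -1.72. Cox6a2 less Cox6a1 stood at -0.39 and Cox8b less Cox8a at 0.07. The LPtau average joined pairs of both signs, with Myh4 less Myh3 at -0.92 (SE 0.53) and Eef1a2 less Eef1a1 at -0.22. In LPtau, Cox8b less Cox8a stood at 1.27 (SE 0.74), Cox6a2 less Cox6a1 at 0.46 and Cox7a1 less Cox7a2 at 0.09. Cox7a1 and Eef1a2 had been called lower before the pairs were chosen, so the pairs do not test a delay independently. The early forms were not higher in LP, at -0.32 for Cox6a1, -0.39 for Cox7a2, -0.44 for Cox8a and -0.22 for Myh3, with only Eef1a1 at 0.18. The lower difference thus came mainly from the mature forms, and a delay stays a hypothesis.

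Cell cycle genes were lower in LP liver, which could reflect fewer dividing erythroid cells. The difference of the list mean was -0.56 (SE 0.26) without and -0.36 (SE 0.16) with the erythroid list mean as a covariate. Most of the estimate remained, but against its SE it is too uncertain to exclude fewer erythroid cells as the whole cause.

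Liver and muscle arrays of the same diet and number had the same sex by expression in 12 of 12 cases, which could mean that the same pup gave both tissues. With sex-linked genes left out, the deviations of such arrays from their group means correlated at a mean of 0.0827, with 12 of 12 above 0, and those of other numbers of the diet at -0.0395. An exact permutation of the numbers within diets gave a one-sided p of 0.0023, which is consistent with shared pups. The labels do not state it.

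Splits of the 6 arrays of 2 groups number 10, too few for a share under 5%, and only the real count and the highest other are given. LPtau against LP liver gave 12 and 0, NPtau against NP liver 0 and 1, LPtau against NP liver 0 and 0, LP against NP muscle 23 and 0, LPtau against LP muscle 4 and 1, and NPtau against NP and LPtau against NP muscle 0 and 0 each. Every split reaches a real count of 0, so the 10 of 10 splits in those comparisons, and the 100 of 100 drawn splits of the interaction in both tissues, test nothing. The highest other split of the interaction called 1405 genes in liver, the next 9, and 1 in muscle. The split with 1405 set LP replicates 1 and 2 with LPtau replicate 2 against NP replicates 1 and 2 with NPtau replicate 1. It also set NPtau replicate 2, LP replicate 3 and LPtau replicate 1 against NP replicate 3, NPtau replicate 3 and LPtau replicate 3. It thus parted the arrays by protein diet except for NPtau replicate 2 and LPtau replicate 3. Whether the diet, erythroid cells or another trait of the samples gave the 1405 genes was not tested.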
